A study of Mus musculus with 22 samples.

How the data were processed

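RNA of 12 pancreatic tumors and 10 cancer cell lines of mice was sequenced, with genotype (miR-21 knockout, KO, or wild type, WT) as given by the labels. Per the labels, RNA was extracted with TRIzol, libraries were made with a stranded mRNA kit, and single-end reads of 75 bases were taken. Lines had been passaged at least 8 times and were used at passage 10 to 14 in 5% serum. Per the labels, the authors made reads with bcl2fastq (1.9.0), trimmed them with Trim Galore and aligned them to mm10 with STAR, for which no version is given. The deposited values are read counts per gene, made by the authors from these alignments, and the labels give neither the strand setting nor the annotation of the counting. Each table holds 53342 genes, of which 53237 have a symbol and 105 (0.00944% of counts) do not.

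Library totals ran from 24547650 to 31118113 counts, and CPM below are counts scaled to the library total and TMM factor, except for sex-linked genes and the limit that follows, which use the library total alone. For a gene with 0 counts in the smallest library, up to 0.122 CPM remains possible (3 counts), from counting error alone and without the variation between animals. No 2 libraries had identical columns, and the smallest chi-square per degree of freedom between any 2 libraries was 49.8. None were left out. Gene positions, types and 3′ UTRs came from GENCODE vM21 on mm10.

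Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with its default low-count filter by group, TMM factors, robust quasi-likelihood tests and Benjamini-Hochberg adjustment, with adjusted p under 0.05 as the threshold. Lines (5 KO, 5 WT) and tumors (8 KO, 4 WT) were fitted apart, so 14020 and 18125 genes were tested. The interaction and the difference between tumors and lines used all 22 libraries and 18662 genes. The common biological coefficient of variation was 0.42 in lines and 0.50 in tumors. Groups of the lines and of the tumors overlap in 5 animals by title, and this dependence enters only where an animal block is named (consensus correlation 0.287). Tested on simulated data with 200 changed genes, the fits recovered 0%, 37.9% and 71.2% of genes changed by 0.5, 1 and 2 (log2) in lines, 0%, 16.4% and 57.6% in tumors, 0%, 10.4% and 47.0% for the interaction and 7.46%, 55.2% and 72.7% between materials, with 8 of 80, 1 of 50, 1 of 39 and 3 of 93 calls false.

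The genes named follow a rule written before the data were examined, as were the comparisons, gene lists, tests, thresholds and the alternatives in the last paragraph. In each KO comparison they are the targeted gene, its host gene, Trp53 and published miR-21 targets, then the 10 genes with the largest change in each direction among those that passed at a mean CPM of at least 1, or the 5 with the smallest p values where fewer than 5 passed, and up to 4 members per list by smallest p. For the interaction they are the 5 smallest p values, and between materials up to 4 members per list by mean count. Sex-linked genes enter the rule only through their list, and genes overlapping a named gene are named after their values were seen. Some genes of the rule, and the tests that concern them, are not reported here.

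Sites were 7-mers and 8-mers matching bases 2 to 8 of mature miR-21-5p (22 bases) in the longest annotated 3′ UTR, of at least 20 bases. Genes without a site were drawn 10000 times, matched in 10 bins of UTR length and 5 of expression. The shift of site genes is their median log2 fold change minus the mean of the medians of these draws. It was compared with 358 control 7-mers of the same bases and with every relabelling of the libraries on mean log2 CPM (252 for lines, 495 for tumors, exact). In both comparisons the shift was the median of site genes after subtracting, in each bin, the median of genes without the site. The same relabellings tested the correlation between line and tumor effects. The 37 gene lists were tested with camera at its preset inter-gene correlation of 0.01, with an estimated correlation, and with fry (limma 3.58.1). Of the lists, 26 could be tested in lines and 36 in tumors. The 37 genes of the mitochondrial genome are absent from the deposited tables, so that list was not analysed.

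Correlations over 13395 autosomal genes between the line and tumor titled with the same animal, after centring each group, were 0.376 (KPC190), 0.222 (KPC202) and 0.467 (KPC232), each the highest among the 4 WT tumors, and 0.0719 (KPC21171, rank 2 of 8) and 0.0341 (KPC2157, rank 3 of 8).

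The alternatives set beforehand were RLE and upper quartile factors, other low-count filters, DESeq2 1.42.0, limma-voom with and without quality weights, a non-robust fit, other thresholds, and all libraries in 1 fit. They also included a surrogate variable (sva 3.50.0), a sex factor (Xist above 100 CPM or not), and epithelial and acinar list means as covariates in tumors. The rest were an animal block, 8mer sites only, 7mer-A1 sites included, all annotated UTR bases, and leaving out each library in turn. The surrogate variable, sex factor and list covariates were set beforehand for counts of called genes. Their use for gene lists and site genes was not. Site genes under each alternative were compared with 300 draws. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.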

Results

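RNA sequencing read counts were deposited for 22 libraries from mouse models of pancreatic cancer. Of these, 12 came from whole tumors and 10 from cancer cell lines grown out of such tumors. Per the labels, 8 tumors and 5 lines lacked microRNA-21 (KO), and 4 tumors and 5 lines carried it (WT). By their titles, 5 animals gave both a line and a tumor. The libraries held counts of 53342 genes. Library totals were 24796473 to 31118113 counts in KO lines, 25468350 to 28888902 in WT lines, 24547650 to 30106745 in KO tumors and 27332257 to 29987227 in WT tumors. MicroRNA-21 is a small RNA that lowers mRNAs carrying a match to its seed, and the comparisons ask which mRNAs differed without it in the cancer cells and in the whole tumor.

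The targeted gene, Mir21a (ENSMUSG00000065455.1, build mm10, chromosome 11, 86584067 to 86584158, inside the annotated bounds of Vmp1), had 0 counts in all 22 libraries, WT included. At the smallest library total, a count of 0 allows up to 0.122 CPM (counts scaled to the library total), or 3 counts, by counting error only. The gene spans 92 bases, lies on the same strand as Vmp1 and, per the labels, library RNA was sheared into longer pieces. How reads within both genes were counted is not given. The 0 counts therefore do not bound its transcripts, and these libraries check no genotype label.

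In the KO lines, Cdip1, which encodes a p53-induced pro-apoptotic protein, and Rnf167, which encodes a ubiquitin ligase of endosomes and lysosomes, rose. Cdip1 (ENSMUSG00000004071.12, chromosome 16, 4750348 to 4790292) stood at 79.9 ± 4.33 CPM in KO and 34.5 ± 6.02 CPM in WT lines (SD, n = 5 each). Its log2 fold change was 1.21 ± 0.14 (SE), with an adjusted p of 0.0282. Rnf167 (ENSMUSG00000040746.15, chromosome 11, 70647235 to 70651421) stood at 63.1 ± 9.22 CPM in KO and 24.7 ± 5.11 CPM in WT lines, a log2 fold change of 1.36 ± 0.17 with an adjusted p of 0.0403. For both genes all 5 KO lines exceeded all 5 WT lines, an order that small p values favour. Chance gives it to 1 gene in 0.397% of splits, or to 55.6 of the 14020 genes, and 102 showed it. The opposite order, as likely by chance, was shown by 70 genes. The longest annotated 3′ UTR of Cdip1 holds an 8mer miR-21 site and that of Rnf167 a 7mer-m8 site. Each overlaps a gene on the opposite strand, and the labels do not give the strand setting of the counting. Hmox2, which overlaps Cdip1, had a log2 fold change of 0.07, and Slc25a11, which overlaps Rnf167, one of -0.21.

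**Figure D1:**
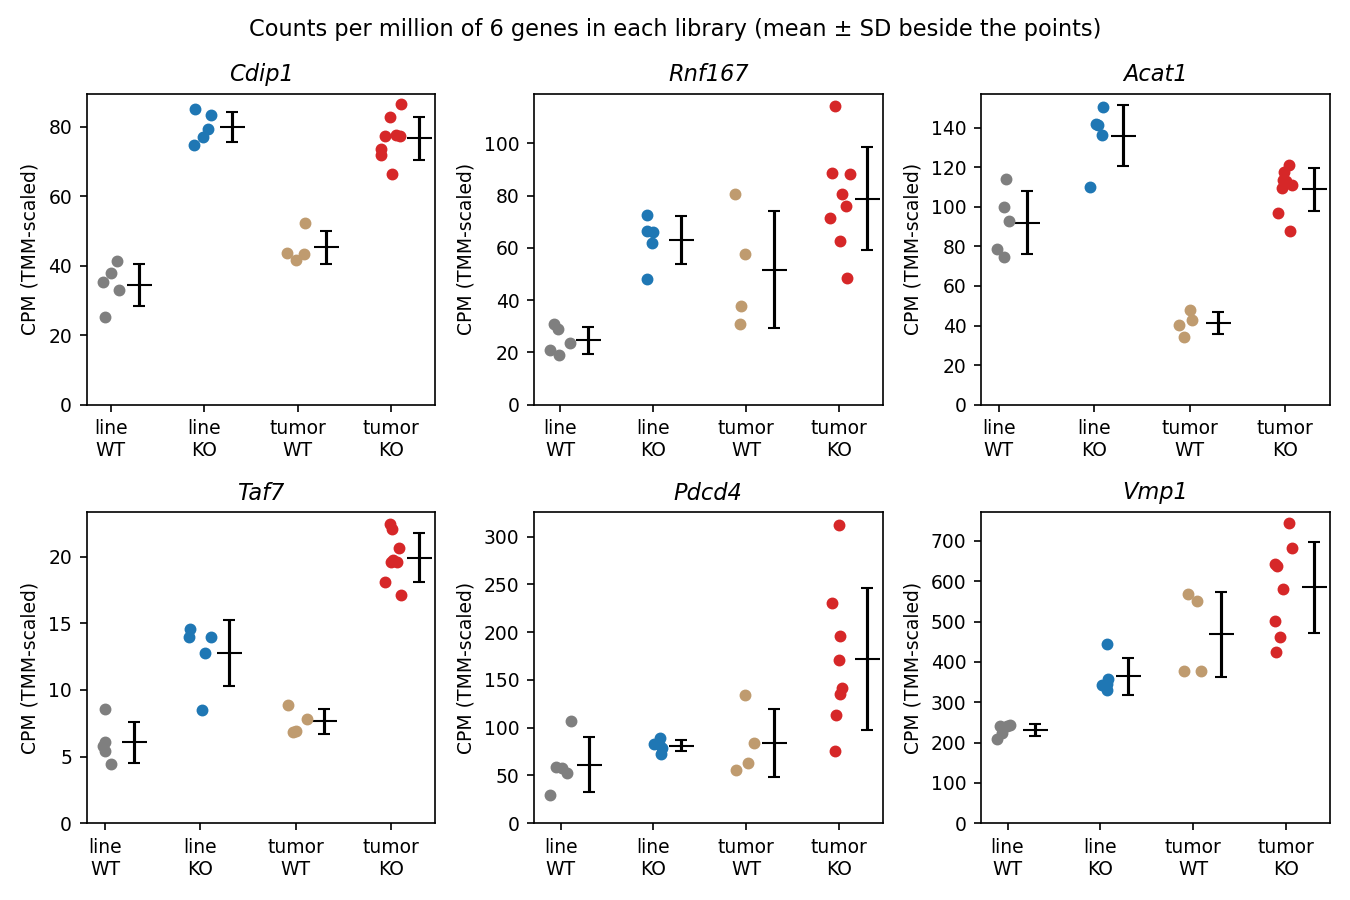
CPM (TMM-scaled) of Cdip1, Rnf167, Acat1, Taf7, Pdcd4 and Vmp1 in each of the 22 libraries, with 1 point per library and the mean ± SD beside each group. Cdip1 stood at 79.9 against 34.5 CPM in KO and WT lines, and Acat1 at 109 against 41.3 CPM in KO and WT tumors.

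With edgeR quasi-likelihood tests on 14020 genes, these 2 genes rose in KO lines and 0 fell. At an unadjusted p under 0.05, 476 genes were higher and 504 lower, where chance alone gives about 701 in all. DESeq2 called 35 higher and 11 lower, and limma-voom 2 in all. Leaving out 1 library ended both calls except for WT lines 3 and 4. Without WT line 3 both genes were called, without WT line 4 only Cdip1, and in the other 8 fits 649 to 1457 genes had an unadjusted p under 0.05. The log2 fold change of Cdip1 stayed between 1.12 and 1.29 over its alternatives and that of Rnf167 between 1.27 and 1.45, with adjusted p up to 0.168 and 0.225. In simulated tables of this design, 37.9% of genes changed by 1 on the log2 scale and 0% of those changed by 0.5 were recovered.

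The genes with the next smallest p values in KO lines did not pass the test. On the higher side these were Tmie, needed for hair-cell mechanotransduction (log2 fold change 1.70, adjusted p 0.260), Vmp1, an autophagy gene that holds Mir21a (0.65 ± 0.11, adjusted p 0.299), and Ubl4a, a chaperone of tail-anchored proteins (0.69, adjusted p 0.464). Tmie overlaps Als2cl on the opposite strand, whose counts were 1285% of its own and whose log2 fold change was 0.50. Without the strand setting of the counting, the Tmie value is in doubt. Ubl4a overlaps Slc10a3 on the same strand, whose counts over all libraries were 27.8% of its own. Vmp1 stood at 364 ± 45.6 CPM in KO and 232 ± 15.1 CPM in WT lines, with all 5 KO lines above all WT lines. On the lower side, Myo15b (-0.86), Igsf11 (-1.30), Chuk, an NF-kappaB kinase (-0.46), Ankrd52 (-0.54) and Tmem267 (-1.50) each had an adjusted p of 0.545, and Myo15b and Ankrd52 also overlap counted genes on the opposite strand. Trp53, the p53 tumor suppressor gene, had a log2 fold change of 0.56 (adjusted p 0.754). Among published miR-21 targets fixed in advance, Pdcd4, a translation inhibitor, had 0.40 (0.746), Reck, an inhibitor of matrix proteases, 0.42 at under 1 CPM (0.920), Spry1 0.63 (0.713), Spry2 0.25 (0.801) and Timp3 0.20 (0.972), with adjusted p in parentheses.

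Genes with a miR-21 site lay slightly higher in KO lines. The 982 searched genes with an 8mer or 7mer-m8 site had a median log2 fold change of 0.04, against -0.02 for genes without a site drawn at matched UTR length and expression, a shift of 0.06. In none of 10000 matched draws was the median as high, and 0 of 358 control 7-mers of the same bases gave as large a shift. Genes with an 8mer were shifted by 0.12, those with a 7mer-m8 by 0.04. Genes are not independent, however, and relabelling the libraries gave a shift as large in either direction in 34 of 252 cases (exact two-sided p = 0.135). The camera p was 0.0128, and 0.188 with an estimated correlation.

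Of the 26 lists that could be tested in lines, 3 passed camera with its preset correlation. None passed with an estimated correlation or with fry (fry adjusted p 0.367 or more). The published miR-21 targets rose as a list, with 23 of 30 members positive and a median log2 fold change of 0.20 (camera adjusted p 0.00117, adjusted p = 0.505 with an estimated correlation). Of its members, Ski, a repressor of TGF-beta signalling, had 0.64, Cdc25a, a cell-cycle phosphatase, 0.57, and Tgfbr2 0.55. The immediate early list, genes induced within minutes of stimulation, also rose, with 9 of 11 members positive and a median of 0.44 (0.00190, adjusted p = 0.505 with an estimated correlation). Btg2, an antiproliferative gene in both lists, had 0.71, Jun 0.55, Zfp36 0.49 and Egr1 1.25. The proliferation list fell, with all 22 members negative and a median of -0.37 (1.2e-05, adjusted p = 0.748 with an estimated correlation). Its DNA replication genes Mcm5 and Mcm7 had -0.72 and -0.40, and the mitotic kinase gene Bub1 had -0.47. No member of these lists was called over all genes or adjusted over the list alone. Single WT lines moved these medians by over 1.5 times. The target median was 0.38 without WT line 3, 0.12 without WT line 4 and 0.10 without WT line 5, the proliferation median -0.17 without WT line 4, and the immediate early median 0.29 without WT line 3, and each list kept its call.

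The other 23 lists did not pass in lines. Those for epithelial ductal genes (median 0.13), classical gastric genes (0.44), mesenchymal genes (-0.03), MAPK output (0.08), p53 targets (-0.07), matrix (0.19), TGF-beta response (-0.01), hypoxia and glycolysis (-0.19) and cytokines (0.46) had camera adjusted p of 0.0744 or more. Stromal and immune lists, with 3 to 6 measured members each, had medians of -0.10 (fibroblast), -0.11 (myofibroblast), -0.31 (inflammatory fibroblast), -0.16 (endothelium), 0.18 (macrophage) and -0.03 (dendritic cell). Medians were 0.19 for basal squamous genes, -0.14 for the interferon response, 0.09 for antigen presentation, -0.02 for Hedgehog and stromal ligands, -1.06 for hepatocytes, 0.53 for mesothelium, -0.05 for Schwann cells and -0.49 for sex-linked genes. For the cytokines the median and test were positive and the mean was -0.05, and for macrophages the mean was -0.04. For myofibroblasts the median was negative and the mean (0.61) and test positive, and for inflammatory fibroblasts, TGF-beta response, endothelium, Schwann cells and sex-linked genes the test was positive with a negative median and mean. Adjusted over the list alone, 1 mesothelial and 1 inflammatory fibroblast gene rose and 1 hepatocyte gene fell, against none over all genes. The sign of a median need not be that of the test, as for inflammatory fibroblasts over all lines (median -0.31, test positive). Some of these lists passed without 1 line, and are given with their medians. They were inflammatory fibroblasts without KO line 4 (-0.19, camera adjusted p 0.0356) or WT line 3 (1.98, 0.0290), basal squamous genes without WT line 5 (0.47, 0.0493), cytokines without KO line 4 (0.36, 0.0216) or WT line 2 (0.54, 0.0158), and mesothelium without WT line 3 (0.83, 0.0386) or WT line 5 (0.99, 0.0263).

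In KO tumors, Acat1, which encodes a mitochondrial enzyme of ketone and isoleucine breakdown, and Taf7, which encodes a subunit of the general transcription factor TFIID, rose. Acat1 (ENSMUSG00000032047.5, chromosome 9, 53580522 to 53610382) stood at 109 ± 11.03 CPM in 8 KO and 41.3 ± 5.76 CPM in 4 WT tumors (SD), a log2 fold change of 1.40 ± 0.13 (SE) with an adjusted p of 0.00142. Taf7 (ENSMUSG00000051316.8, chromosome 18, 37640491 to 37644204) stood at 19.9 ± 1.82 against 7.63 ± 0.938 CPM, a log2 fold change of 1.38 ± 0.15 with an adjusted p of 0.00380. Cdip1, called in lines, stood at 76.6 ± 6.25 against 45.3 ± 4.76 CPM, and its 0.76 ± 0.11 had an adjusted p of 0.0572. Tprgl, a presynaptic protein gene (0.88), and Spg20, which encodes the hereditary-spastic-paraplegia protein spartin (0.84), each had an adjusted p of 0.0685. Tprgl overlaps Wrap73 on the opposite strand, whose counts over all libraries were 16.0% of its own. For all 5 genes each of the 8 KO tumors exceeded each WT tumor, an order that small p values favour, and each of the 5 has an 8mer site. Chance gives this order to 1 gene in 0.202% of splits, or to 36.6 of the 18125 genes, and 207 showed it. The opposite order, as likely by chance, was shown by 167 genes.

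Lower genes in KO tumors did not pass the test. The 5 with the smallest p values were Nat8l, the N-acetylaspartate synthase (-3.00), Pla2g6, a phospholipase (-0.95), Atp2a1, the calcium pump of fast muscle (-8.02), Baz1a, a chromatin remodeller (-0.71), and Dlk1, a Notch-like imprinted gene (-5.02), with adjusted p of 0.0685 to 0.0754. Atp2a1 stood at 0.423 ± 0.146 CPM in KO and 111 ± 214 CPM in WT tumors, where WT tumor 3 alone had 433 CPM, and it too overlaps a counted gene on the opposite strand. Reck had a log2 fold change of 2.55 ± 0.58 (14.9 ± 9.01 against 2.54 ± 1.29 CPM, adjusted p 0.123), Pdcd4 of 1.03 (0.201), Timp3, a metalloproteinase inhibitor, of 0.83 (0.221) and Spry1, an inhibitor of receptor kinase signalling, of 0.68 (0.231). Spry2 had -0.09 (0.909), Vmp1 0.32 (0.403), Trp53 0.41 (0.595) and Rnf167 0.61 (0.277).

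The edgeR quasi-likelihood tests on 18125 genes called these 2 genes higher and 0 lower in KO tumors. At an unadjusted p under 0.05, 1512 genes were higher and 1521 lower, where chance alone gives about 906. Over all 12 tumors, Cdip1 also passed with upper quartile factors, a mean CPM of at least 1, limma-voom with and without quality weights, and a surrogate variable. It did not with RLE factors, no low-count filter, a non-robust fit, the sex factor or a list covariate. Without KO tumor 2, KO tumor 8 or WT tumor 2 Cdip1 also passed (0.0286, 0.0488 and 0.0435), and without KO tumor 2 or WT tumor 2 Tprgl, Nat8l, Pla2g6, Atp2a1, Baz1a and Dlk1 did (0.0210 to 0.0452). Without KO tumor 2, Spg20 (0.0177) and Reck (0.0400) passed, and without WT tumor 4 Atp2a1 (0.0353). Limma-voom called 4 genes, all higher, and DESeq2 550 higher and 339 lower. Acat1 and Taf7 were called in all 12 fits with 1 tumor left out, in which counts ran from 2 to 82, with 82 without KO tumor 2, 57 without WT tumor 2, 6 without WT tumor 4 and 4 without KO tumor 8. Both stayed called over all 12 tumors with the acinar or the epithelial ductal list as covariate (2 and 4 genes called). Neither was called without KO tumors 4 and 8 and WT tumor 4, the 3 with the highest acinar list means, where the edgeR test gave 0 genes, 1825 at an unadjusted p under 0.05, and log2 fold changes of 1.28 and 1.39 (adjusted p 0.0877 and 0.153). Over all their alternatives adjusted p ran up to those values.

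Site genes were higher in KO tumors. The 1163 searched genes with an 8mer or 7mer-m8 site had a median log2 fold change of 0.12, against 0.01 in matched draws, a shift of 0.11. None of 10000 matched draws and 0 of 358 control 7-mers were as high. The shift was 0.21 for genes with an 8mer, of which 71.4% were positive, and 0.08 for those with a 7mer-m8. On mean log2 CPM, the shift under the labels as given was larger than under any other of the 495 relabellings (exact two-sided p = 0.00202, the smallest they can give). The camera p was 3.1e-04, and 5.8e-04 with an estimated correlation.

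**Figure D2:**
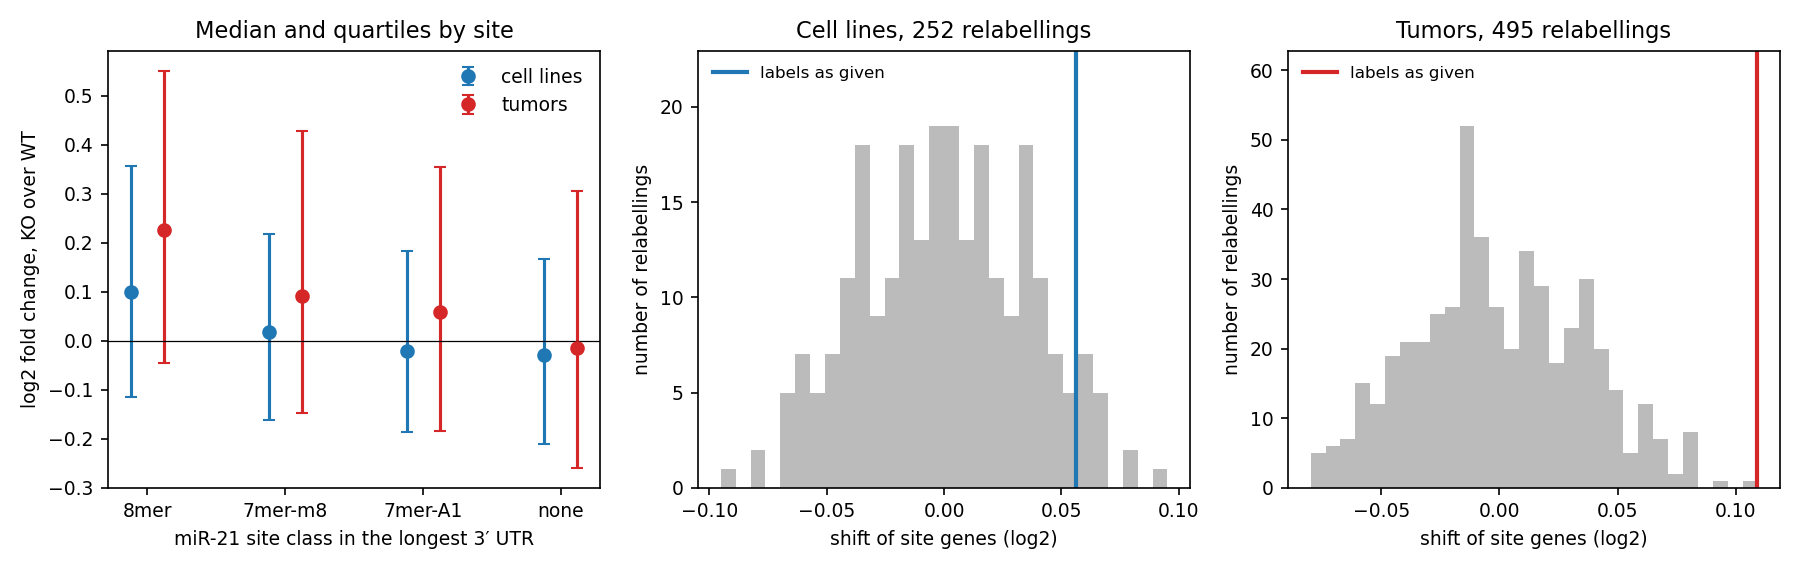
Left, median and quartiles of the log2 fold change (KO over WT) by miR-21 site class in the longest 3′ UTR, in cell lines and tumors. Middle and right, number of relabellings of the libraries by the shift of site genes (log2) they gave, with the labels as given as a line; 34 of 252 line relabellings were as large in either direction, and 1 of 495 tumor relabellings.

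In KO tumors the proliferation list fell, with all 22 members negative and a median log2 fold change of -0.59 (camera adjusted p 3.4e-08, adjusted p = 0.697 with an estimated correlation). Its mitotic kinase genes Aurkb and Aurka had -1.06 and -1.08, and the replication clamp gene Pcna -0.39. The epithelial ductal list fell, with 12 of 15 members negative and a median of -0.50 (0.00350, adjusted p = 0.697 with an estimated correlation). Adjusted over the list alone, the keratin genes Krt18 (-1.27), Krt7 (-1.08) and Krt8 (-0.96) fell, against none over all genes. The basal squamous list fell, at -1.17 (0.00474, adjusted p = 0.697 with an estimated correlation), and adjusted over the list alone 3 genes fell, among them the laminin genes Lama3 (-1.76) and Lamb3 (-1.29). Also lower were the lists for MAPK output (-0.43, with Dusp5 at -1.39 and Myc at -0.70; 0.00605, adjusted p = 0.701 with an estimated correlation) and for hypoxia and glycolysis (-0.44; 0.00474, adjusted p = 0.701 with an estimated correlation). In the last, adjusted over the list alone, the glycolysis genes Aldoa (-0.73) and Hk2 (-1.08) fell. The cytokine list fell at -0.18 (0.0148, adjusted p = 0.697 with an estimated correlation).

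Other lists rose in KO tumors. The published miR-21 targets had 21 of 30 members positive and a median of 0.26 (0.00874, adjusted p = 0.227 with an estimated correlation, fry adjusted p 0.00440), and the mean of the list in each KO tumor was above that in each WT tumor. No other list, higher or lower, passed fry in tumors (adjusted p 0.213 or more). Adjusted over the list alone, Reck (2.55) and Ski (0.47) rose, and Jag1, a Notch ligand (-1.62), and Rhob, a small GTPase (-0.90), fell. The Hedgehog and stromal ligand list rose at 0.71 (0.00982, adjusted p = 0.697 with an estimated correlation). Its transcription factor genes Gli2 (1.50) and Gli1 (2.16) were among the 3 that rose adjusted over the list alone. The mesothelial list rose at 1.69 (0.00350, adjusted p = 0.697 with an estimated correlation), with Wt1 (1.78) and Rspo1 (2.58) among the 3 that rose adjusted over the list alone. The islet list rose at 4.54 (0.00277, adjusted p = 0.697 with an estimated correlation). Adjusted over the list alone, 4 islet genes rose, among them the hormone genes Sst (5.09), Ppy (5.63) and Ins2 (5.11). The acinar list rose at 1.84 (0.00454, adjusted p = 0.701 with an estimated correlation), with Cela1, an elastase, at 1.66 and Ctrb1, a chymotrypsinogen, at 2.45. The erythroid list rose at 0.79 (0.0282, adjusted p = 0.701 with an estimated correlation). The skeletal muscle list fell at -5.75 (0.00443, adjusted p = 0.697 with an estimated correlation), and its 6 measured members, Acta1 (-7.73) and Mylpf (-3.76) among them, fell adjusted over the list alone.

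**Figure D3:**
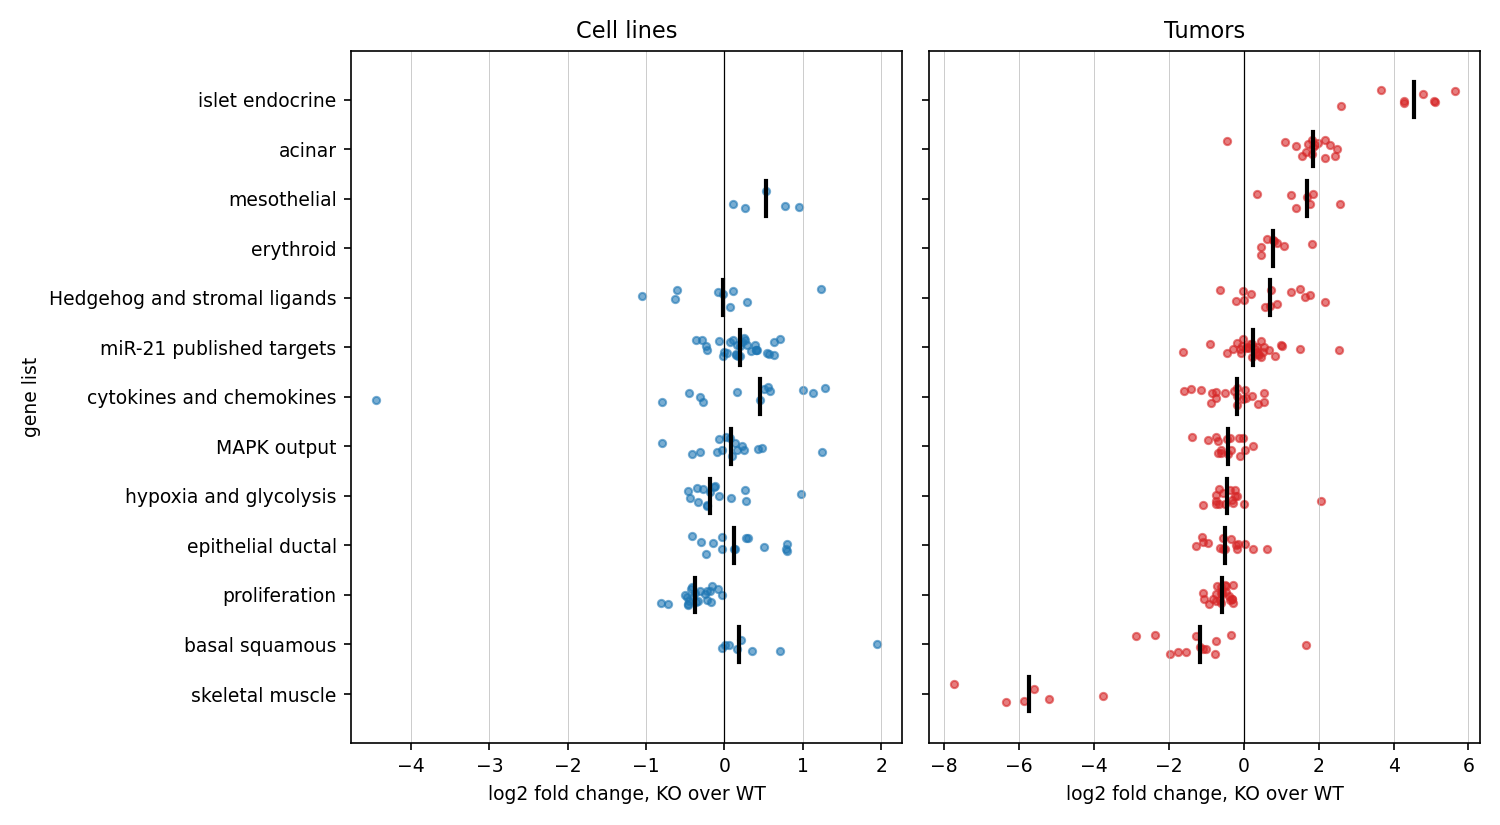
Log2 fold change (KO over WT) of each measured member of the 13 lists that passed camera with its preset correlation in tumors, with 1 point per gene and the median as a bar, in cell lines (left) and tumors (right, on a wider axis). The islet, acinar and erythroid lists and the skeletal muscle list had too few measured members to test in lines.

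Single tumors carried several of these lists. The skeletal muscle list mean was 7.26 log2 CPM in WT tumor 3 and 2.26 in WT tumor 1, and without WT tumor 3 its median log2 fold change was -1.09. Acinar list means were highest in KO tumors 4 (6.03) and 8 (3.97) and WT tumor 4 (3.86). The acinar median was 0.63 without KO tumor 4 and 4.93 without WT tumor 4, and the islet median 7.87 without WT tumor 2. Without WT tumor 1, the MAPK median was -0.20 and the hypoxia median -0.18 (camera adjusted p 0.202 and 0.105), and the basal squamous median -0.62. The cytokine median was -0.69 without KO tumor 8, -0.28 without WT tumor 1, -0.30 without WT tumor 3, and -0.22 without WT tumor 2, where its call was lost (0.0522). The erythroid median was 0.51 without KO tumor 4 and 1.33 without WT tumor 4, and its call was lost without KO tumor 2 (0.83, 0.0820), WT tumor 1 (0.59, 0.181) and WT tumor 2 (0.64, 0.172).

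Some list calls were lost when the mean of another list entered the fit. With the acinar list as a covariate the MAPK (median -0.23, camera adjusted p 0.212), hypoxia (-0.12, 0.339), basal squamous (-0.70, 0.0600), Hedgehog (0.44, 0.0842) and erythroid (0.46, 0.223) lists lost their calls. Basal squamous genes (-1.54, 0.0511) and cytokines (-0.32, 0.110) lost them with the epithelial list as a covariate, with medians further from 0 than without it. The MAPK list also lost its call without the 3 tumors richest in acinar transcripts (-0.30, 0.119).

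**Figure D4:**
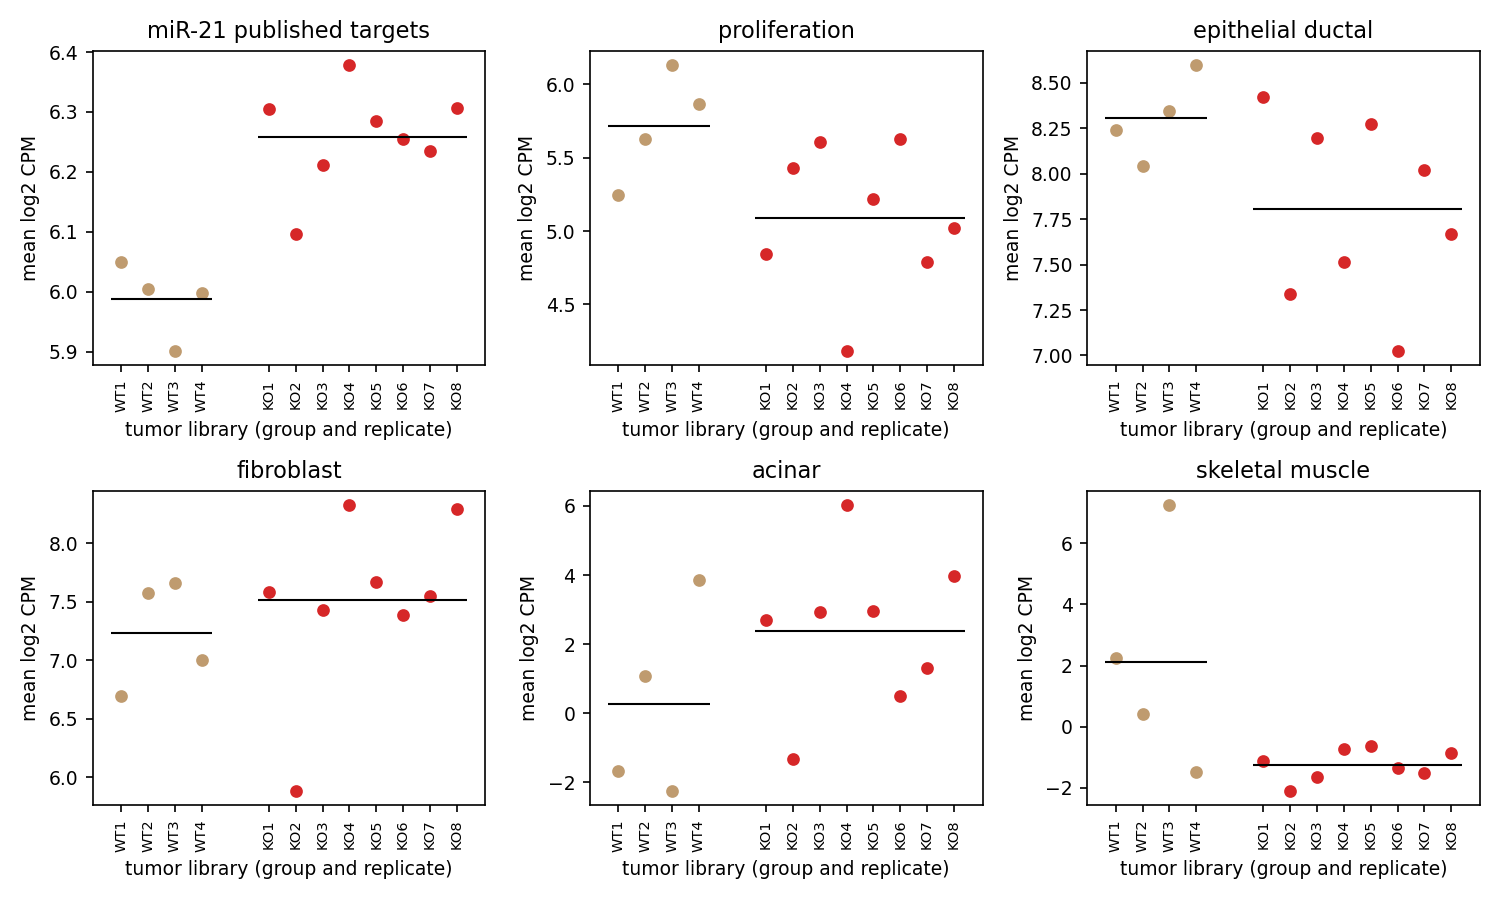
Mean log2 CPM of 6 gene lists in each of the 12 tumor libraries, with 1 point per library and a line at the mean of the 4 WT and of the 8 KO tumors; each axis has its own range. WT tumor 3 had a skeletal muscle mean of 7.26 and KO tumor 4 an acinar mean of 6.03.

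Cell types of the stroma did not pass in tumors as lists with all 12 libraries and no covariate. The fibroblast list had a median of 0.23 (camera adjusted p 0.250), and adjusted over the list alone Thy1 (1.16) and Pdgfra (1.55), both surface markers of fibroblasts, rose and the activation marker Fap (-1.15) fell. That list passed without KO tumor 2 (0.35, 0.00451) and without WT tumor 3 (0.46, 0.0220). Medians of the other lists that did not pass were 0.36 for myofibroblasts, -0.03 for inflammatory fibroblasts, 0.19 for matrix, -0.16 for TGF-beta response, 0.19 for endothelium, -0.13 for pericytes and 0.23 for macrophages. They were 0.45 for neutrophils, 0.50 for T and NK cells, 0.13 for B and plasma cells, 0.33 for dendritic cells, -0.46 for mast cells, -0.38 for the interferon response and 0.33 for antigen presentation. They were -0.31 for classical gastric genes, 0.42 for mesenchymal genes, 0.15 for p53 targets, -0.16 for immediate early genes, -0.37 for adipocytes, 0.03 for hepatocytes, 0.41 for Schwann cells and -0.14 for sex-linked genes. For neutrophils, T and NK cells, dendritic cells and endothelium the camera direction was down although the median and the mean were positive. For B and plasma cells (mean -0.08) and hepatocytes (mean -0.52) the median alone was positive, for inflammatory fibroblasts (mean 0.50) it alone was negative, for classical gastric genes the test alone was positive, and for sex-linked genes the mean alone was (2.14).

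Several of these lists passed in other fits of the tumors, some with a median of the other sign. Macrophages had -0.34 with the acinar covariate (camera adjusted p 0.0452). Without the 3 tumors richest in acinar transcripts, T and NK cells had -1.83 (0.00679), B and plasma cells -2.71 (0.0118), endothelium -0.21 (0.0331), adipocytes -2.45 (9.8e-04) and myofibroblasts 1.41 (0.0264). Without KO tumor 8, T and NK cells had -1.20 (0.0411), the interferon response -0.66 (0.00254), adipocytes -1.07 (0.00550) and immediate early genes -0.23 (0.0411). Without WT tumor 3, the interferon response had -0.69 (1.6e-05), matrix 0.29 (0.0122) and immediate early genes -0.22 (0.0220). Myofibroblasts had 1.41 (0.0293) without WT tumor 4, and adipocytes -0.74 (0.00636) without KO tumor 4 and -0.72 (0.00132) without WT tumor 1. Immediate early genes had -0.16 (0.0467), -0.22 (0.0173) and -0.32 (0.0182) without KO tumor 1, KO tumor 5 and WT tumor 2.

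The difference between the KO effects in tumors and in lines was tested as an interaction over all 22 libraries. No gene passed the edgeR quasi-likelihood test among 18662, with 981 higher and 559 lower at an unadjusted p under 0.05 (933 by chance), while DESeq2 called 67 and limma-voom with a block by animal 0. Acat1, 1 of the 5 smallest p values, had a larger rise in tumors than in lines by 0.86 ± 0.18 on the log2 scale (adjusted p 0.299). Magix (4.24, under 1 CPM in all groups), the receptor kinase gene Ret (-2.66), Spats2l (2.58) and the muscle actin gene Acta1 (-9.06) had the same adjusted p. Cdip1 had -0.42 (0.473), Rnf167 -0.72 (0.598) and Taf7 0.34 (0.757), so the calls of 1 material and not the other are not shown to differ between them. The site genes had a shift of 0.06, and 2 of 10000 matched draws were as high. After centring by bin, as for the control 7-mers, the shift was 0.041, which 92 of the 358 controls reached. Without KO line 2, 1 gene, Magix, was called.

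Of the lists tested for the interaction, 10 passed camera at its preset correlation. None of them passed with an estimated correlation (adjusted p = 0.366 or more) or with fry (0.243 or more), so none is taken as a difference between materials. A median below 0 means a lower KO effect in tumors than in lines. Those lists were immediate early genes (median -0.52, camera adjusted p 2.6e-04, adjusted p = 0.366 with an estimated correlation), MAPK output (-0.57, 2.6e-04, 0.632), basal squamous (-1.29, 0.00168, 0.366), islet (5.13, 0.00289, 0.879) and epithelial ductal (-0.64, 0.00289, 0.672). The others were Hedgehog (0.83, 0.00773, 0.366), proliferation (-0.18, 0.0104, 0.994), cytokines (-0.58, 0.0104, 0.647), skeletal muscle (-5.22, 0.0309, 0.936) and hypoxia (-0.14, 0.0395, 0.994). No fit with a library left out was made for these lists.

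Across genes, the KO effects of lines and tumors had a weak correlation, no larger than relabelling the libraries often gave. All 4 genes called in either material had the same sign in both. Over 13818 genes Pearson's r was 0.0958 and Spearman's rho 0.194, and 59.2% of genes had the same sign. Higher at an unadjusted p under 0.05 in both were 76 genes, where 31.4 are expected, and lower in both 99, where 49.3 are expected, with 28 in opposite directions. Of the 74 genes higher in both with a searched UTR, 27 (36.5%) had an 8mer or 7mer-m8 site, against 8.03% of all 12173 genes (Fisher's exact test, odds ratio 6.74, p = 5.6e-12), and of 92 lower in both, 3 had a site. Genes are not independent replicates, and the expected numbers and Fisher's test take lines and tumors as independent, while 5 animals gave both. An overlap with only the 5 lines whose animals gave no tumor was added after the data were seen. It held 67 genes higher in both (43.6 expected) and 71 lower in both (53.5 expected). In opposite directions, 45 were higher in lines and lower in tumors and 57 the reverse. No expected numbers were computed for opposite directions, so an excess there is not excluded. Of 65 higher in both with a searched UTR, 16 (24.6%) had a site, against 8.00% of all genes (Fisher's exact test, p = 3.8e-05), and of 67 lower in both, 1 had. Relabelling the lines against the tumor effects, on mean log2 CPM, gave a Pearson correlation of either sign as large as the observed 0.184 in 96 of 252 cases (exact p = 0.381, Spearman 0.246), and relabelling the tumors in 129 of 495 (0.261, Spearman 0.194). Pearson's r fell to -0.0474 in the 5 lines whose animals gave no tumor, was 0.244 without WT line 3, and was 0.0363, 0.0386, 0.0453 and 0.0479 without WT line 4, WT tumor 3, KO line 4 and WT line 1.

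Whole tumors differed from lines in 12227 of 18662 genes, with 7187 higher and 5040 lower in tumors by edgeR quasi-likelihood tests, and material and count table cannot be told apart. The added cell types were plain. All 18 fibroblast genes were higher, Col1a1, a fibrillar collagen, by 9.71 ± 0.54 on the log2 scale (in CPM scaled with TMM factors over all 22 libraries, 1985 ± 970 CPM in KO and 1912 ± 991 CPM in WT tumors, against 2.02 ± 1.03 and 2.65 ± 3.07 CPM in KO and WT lines). All 15 endothelial genes were higher, Pecam1 by 7.47 ± 0.34, as were 8 of 8 pericyte, 14 of 15 macrophage, 16 of 16 T and NK cell, 12 of 12 B and plasma cell, 15 of 16 acinar and 8 of 8 islet genes. Lyz2, a macrophage lysozyme, stood on the same scale at 1039 ± 568 CPM in KO and 831 ± 456 CPM in WT tumors and had no count in any line. All 22 proliferation genes were lower in tumors (median -1.88), Top2a by -2.08 ± 0.26. Of 16 MAPK output genes, 9 were lower, with Myc at -1.30 ± 0.20. Of 15 epithelial ductal genes, 8 were higher and 3 lower in tumors (median 0.89). With the animal as a block over the 5 animals titled with both materials, 7982 genes differed, of which 7627 were among the 12227, and over 4 of them, without KPC2157, 6488.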

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

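The comparison of the 2 KPC2157 libraries, the search of the Vmp1 UTR, the share of higher genes near the locus, the places of the 4 called genes and the counts of splits at an unadjusted p under 0.05 were tests chosen after the result was seen. Single libraries far from the rest of their group were sought in 339 groups of values (named genes and list means), by the gap to the nearest library over the range of the group. Such a gap was found in 35, where a chance rate of 1 in 20 would give about 17. That rate holds for normally distributed values, and whether CPM are so distributed was not tested. Any single gap can be chance. Values are CPM unless stated, with the nearest library of the group in parentheses.

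Trp53 was far above its group in KO line 5 (15.4, nearest 6.69), KO tumor 8 (78.9, nearest 29.8) and WT tumor 2 (34.1, nearest 21.7). Vmp1 was highest in KO line 3 (444, nearest 358), Btg2 in KO line 4 (91.1, nearest 58.6) and Rhob in WT line 5 (216, nearest 108). WT line 3 stood apart in Timp3 (265, nearest 33.5), Jun (35.4, nearest 21.8), Col1a1 (7.56, nearest 1.76) and, below the others, Mylpf (0.715, nearest 1.41).

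Among KO tumors, tumor 6 was far above the rest in Spry2 (121, nearest 56.0), Jag1 (189, nearest 113) and the mesenchymal list mean (6.63 log2 CPM, nearest 5.64). Tumor 8 was far above in Ppy (63.5, nearest 21.7), Ins2 (108, nearest 24.98), Col1a1 (4192, nearest 2122) and the dendritic cell (3.42 log2 CPM, nearest 1.13) and antigen presentation (7.90 log2 CPM, nearest 5.78) list means. Tumor 4 was far above in Cela1 (192, nearest 80.4), Gli1 (27.2, nearest 13.0) and Pdgfra (189.7, nearest 104). Tumor 2 was far below in the fibroblast (5.89 log2 CPM, nearest 7.39), inflammatory fibroblast (2.82, nearest 4.06) and matrix (7.43, nearest 8.20) list means. Tumor 3 was far above in Tmem267 (18.3, nearest 6.01) and tumor 7 in Krt8 (1959.9, nearest 1332).

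Among WT tumors, tumor 3 was far above the other 3 in the muscle genes Atp2a1 (433, nearest 8.83), Acta1 (387, nearest 16.2) and Mylpf (63.9, nearest 4.45), and below them in Zfp36 (41.04, nearest 61.7). Tumor 1 was far above in Spry2 (113, nearest 52.5) and Nat8l (48.0, nearest 14.2), tumor 4 in Dlk1 (146, nearest 26.3) and Ctrb1 (210.1, nearest 23.0), and tumor 2 was far below in Aldoa (768, nearest 1195).

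As a test of passenger DNA around the deleted locus for genes higher in KO, in tumors 26.4% of 265 genes within 10 Mb of Mir21a had an unadjusted edgeR p under 0.05, against 16.6% elsewhere (4.29 binomial SD above), but 59 of these 70 were lower in KO, and in lines the share was 4.71% of 191 genes against 7.02% (-1.25 SD). Genes higher in KO at that p, Vmp1 left out, were a smaller share within 10 Mb than elsewhere in lines (1.05% against 3.42%, -1.80 SD) and tumors (4.17% against 8.41%, -2.49 SD). The line share was not low enough by the limit chosen for this test, so passenger DNA stays undecided for these genes. It also stays open for Vmp1 and for lower genes near the locus. The binomial SD takes neighbouring genes as independent and does not measure variation between animals. Of Cdip1, Acat1 and Taf7, 0 lie on chromosome 11, which argues against a direct effect of DNA linked to the locus on these 3 (an indirect one was not tested), while Rnf167 lies on chromosome 11, 15.9 Mb from Mir21a, so linked DNA cannot be told apart from other causes there. Of the 50 genes with the smallest p values on the higher side, 42% in lines (central 95% of matched draws 2 to 16%) and 20% in tumors (4 to 20%, reached in 269 of 10000 draws) had a site. By this share, loss of repression through sites may account for part of the genes in lines and stays undecided in tumors. The draws take genes as independent, and this share was not tested by relabelling the libraries. The site shift was, with an exact two-sided p of 0.135 in lines and 0.00202 in tumors. The UTR of Vmp1 gave 0 searches with an 8mer or 7mer-m8, which argues against direct repression through such sites as the reason for its higher values in KO lines.

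The line and the tumor titled KPC2157 differ in sex-linked transcripts (CPM here on the library total alone, without TMM factors). KO line 5 had no Xist and the Y-linked Ddx3y (8.81), Kdm5d (22.6), Eif2s3y (18.5) and Uty (14.4), and KO tumor 3 had Xist at 1740 and Y-linked genes at 0.0664 or less. All 4 Y-linked genes were above 1 CPM only in the library without Xist, so 1 of the 2 libraries may come from another animal than its title says. Neither held both Xist and Y-linked transcripts (0 libraries), which argues against a mixed library. No biological explanation was tested.

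Splits of the libraries into groups of the same sizes were fitted in the same way, and a result is given as whether chance can be excluded. In lines 3 of 100 splits called at least the 2 genes of the labels as given (highest other 6). This is under 5% for that test alone, without correction for the other split tests. By genes at an unadjusted edgeR p under 0.05, 20 of the 99 other splits of the lines had at least the 980 of the labels as given (highest other 1809). The 2 counts therefore disagree for the lines. Taken alone, the called genes pass the 5% limit and the count at an unadjusted p does not, and chance is not taken as excluded for the lines. In tumors 1 of 100 splits, the labels themselves, called at least as many (2 genes, highest other 1). Taken alone, this excludes chance for the tumor count of called genes at the 5% level. By genes at an unadjusted edgeR p under 0.05, 0 of 99 other tumor splits reached 3033 (highest other 2698). For the interaction the labels as given call 0 genes, so all 100 splits call as many whatever the data, and this count says nothing about chance. Of its 99 other splits 88 called 0 genes, and the highest called 87, which may reflect a structure of the samples that was not tested. Between tumors and lines 1 of 100 did (12227 genes, highest other 3), and chance can be excluded. For the shift of site genes, 17 of 126 splits of the lines were as large in either direction (0.0560, highest other 0.0951) and chance cannot be excluded, while in tumors 1 of 495 was (0.109, highest other 0.0941) and it can.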

How the results depend on the processing

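The leave-one-out fits of tumors against lines and of the correlation, the fits without the KPC2157 libraries, the 4-animal block and the fits without the 3 tumors richest in acinar transcripts were chosen after the data were seen. For gene lists and site genes, the surrogate variable, sex factor and list covariates were not set beforehand either. In lines, 2 genes became 1 with upper quartile factors, a surrogate variable or the sex factor (Cdip1 each time), 46 with DESeq2 (35 higher, 11 lower) and 0 at an adjusted p under 0.01. With all 22 libraries they became 5 (4 higher, 1 lower), where Cdip1 was kept, Rnf167 was lost and Taf7 was among those gained. Without 1 library counts ran from 0 to 2. In tumors, 2 genes became 889 with DESeq2 (550 higher, 339 lower), 4 with limma-voom, 5 with quality weights, 40 with all 22 libraries (10 higher, 30 lower), 5 with a surrogate variable, 4 with the epithelial covariate, 20 at an adjusted p under 0.10, and 0 without the 3 acinar-rich tumors, where fewer libraries were fitted (edgeR, 1825 genes at an unadjusted p under 0.05). Without 1 library counts ran from 2 to 82. For the interaction, 0 genes became 67 with DESeq2 (49 higher, 18 lower), and counts ran from 0 to 1 without 1 library. Between materials, 12227 genes became 7982 with a block over 5 animals and 6488 over 4, with fewer libraries. The correlation of line and tumor effects went from 0.0958 to -0.0474 without the lines whose animals gave a tumor (3 KO against 2 WT lines), and ran from 0.0363 to 0.244 without 1 library. The genes called in either comparison are 4, so no correlation was computed for them. The macrophage list in tumors went from a median of 0.23 to -0.339 with the acinar covariate (camera adjusted p 0.0452). Except where fewer libraries were fitted, the cause was not tested. The shift of site genes stayed positive under every alternative, at 0.044 to 0.123 in lines and 0.086 to 0.210 in tumors, highest with 8mer sites only. Over the named genes, 798 values kept their side of the threshold, 48 passed it only under an alternative, 23 lost it, and 0 reversed direction with a pass in either fit. For the lists, by the direction of camera and not of the median, these were 991, 36, 47 and 1. A change of direction where neither fit passed counts among the 798 and the 991, and list medians changed sign more often. Depth was similar in all groups.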

Other observations

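Sex-linked transcripts, in CPM on the library total alone without TMM factors, were unevenly spread over the libraries. Xist, the transcript that silences 1 X chromosome, was above 100 CPM in KO lines 3 and 4 and WT line 3, and in KO tumors 1, 3 and 6, and in no WT tumor. WT line 2 (KPC202) had neither Xist (0.196 CPM) nor Y-linked transcripts (0.0391 CPM or less), while WT tumor 2, titled with the same animal, had Ddx3y at 42.8 CPM. WT line 1 (KPC190) had no Ddx3y, which stood at 15.7 CPM in WT tumor 1. WT lines 4 (KPC232) and 5 had no Eif2s3y, which stood at 10.1 CPM in WT tumor 3 (KPC232). The sex factor used the Xist limit alone, so WT line 2 was placed with the libraries without Xist. In tumors that factor varied only among KO libraries, so it is partly tied to genotype. Apart from this factor, the sex-linked list and the comparison of the KPC2157 libraries, no test was made of these values.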
